A study of Rattus norvegicus with 36 samples.

How the data were processed

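RNA from the left ventricle of 12 rats was measured on 36 Affymetrix expression arrays. There were 4 COP rats, 4 DA rats and 4 F1 rats from a cross of the COP and DA strains, all 15 weeks old. Each animal gave 1 RNA sample that was hybridized to 3 array types, U34A, U34B and U34C, which carry different probe sets, so that an animal and not an array was the replicate. Per the labels, labeled cRNA was made with the Enzo high-yield transcript labeling kit, cleaned on a column and hybridized by the manufacturer's protocol. Single animals were the source of each sample, so the spread between replicates included biological variation. The animals are named here by strain and by the number in their titles. The sex of the animals, the direction of the cross and the time of day of tissue collection were not given in the sources used here.

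The values used were the intensity values that the authors deposited, 1 linear value per probe set and array. Per the labels, these were made with the Affymetrix GeneChip Expression Analysis Software; its version, its settings and any scaling target were not given in the sources used here. Negative values and values near 0 were present, and every array had a 2% trimmed mean of 150.3 (U34A) or 150.1 (U34B and U34C), so the deposited values had already been scaled to a common mean within each array type. A global scaling of this kind assumes that the total signal is alike in all animals and does not correct differences in RNA quality along the transcript. The scaled values were used as deposited, by a rule fixed in advance. Values below the 25th percentile of the positive values of an array type (6.8, 15.5 and 13.7 for U34A, U34B and U34C) were set to that floor and log2 values were taken. A group with all 4 animals at the floor has only an upper bound for its level, and a fold against such a group is given as "at least". The number of arrays limits the precision of every value. No count of molecules lies behind an intensity.

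Of 8799, 8791 and 8789 probe sets on the 3 array types, 177 controls were left out. A probe set was tested if at least 4 of the 12 animals lay above the pooled median of its array type (32.8, 64.4 and 62.4), which left 4702, 4757 and 4707 probe sets, 14166 in all. Genes were named from the platform annotation. Among the 26202 probe sets other than controls, 18178 had 1 gene symbol, 391 had several and 7633 were not in the gene table. Through the Entrez identifier, 18122 of the 18178 matched a gene of the RefSeq annotation of assembly GRCr8, and 0 symbols had to be changed. The tested probe sets included 10905 with 1 symbol, for 7530 genes, and 3261 without a single symbol, which were counted but not named. Chromosomes were taken from the same RefSeq table.

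The 3 array types of an animal were stacked into 1 column of 14166 log2 values, and all 12 animals were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). The contrasts were DA minus COP, F1 minus COP, F1 minus DA and F1 minus the mean of DA and COP on the log2 scale (the mid-parent). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with 0.05 as the threshold, and a probe set past it is called here. All adjusted p-values in the text come from limma. The standard errors are the moderated ones of the fit. The position of F1 between the parents was taken per F1 animal as the median, over the probe sets called between DA and COP, of F1 minus the COP mean over DA minus COP, so that COP is 0 and DA is 1.

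The text names genes by a rule. These are the 12 largest rises and 12 largest falls between DA and COP, up to 5 each way between F1 and each parent and up to 6 each way against the mid-parent. All were probe sets with 1 symbol past the threshold, and for the comparisons of 2 groups all 4 animals of one group had to lie above all 4 of the other. Irs2 and Pik3r1, named as keywords in the labels, were always reported, as were up to 4 called members of each gene list and the 2 brightest members of each list of markers for other cell types. Where a gene had several probe sets, the one with the largest change was named, and for the gene lists the brightest. In all, 30 gene lists were fixed, of which 27 had at least 5 measured genes and were tested with camera of limma at a preset correlation of 0.01 between genes. The same lists were tested with the correlation estimated and with fry. The list of mitochondrial genome genes, that of mesothelium and epithelium markers and that of sex-linked genes had too few measured genes. Genes on each chromosome were compared with all others by a two-sided Fisher's exact test, as a description only, since neighboring genes are not independent. The groups, contrasts, floor, filter, naming rule, gene lists and most alternatives were chosen before the data were examined. Exceptions were the exclusion of ribosomal S6 kinases from the ribosomal protein list, the settings that use the hexokinase control and the settings restricted to animals with numbers under or over 100, all chosen afterwards.

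The alternatives were quantile normalization, a common median per array, lower and higher floors, an offset in place of the floor, no filter and a stricter one, other variance models, a fit of only the groups compared, array weights, the animal number as a covariate, a mid-parent on the linear scale, and each animal left out in turn.

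Before use, the procedure was tested on simulated data with the spread of the real probe sets. For DA against COP it recovered 8, 60, 96 and 100% of 50 probe sets changed by 0.5, 1, 2 and 4 on the log2 scale among 14166, with 4 false calls among 136, and it made 0 calls when nothing had been changed. For F1 against the mid-parent it recovered 16, 78, 98 and 100%, with 4 false calls among 150. Differences under 2-fold were thus often missed with 4 animals per group. The simulated values varied independently between probe sets, with the same spread in every group and no floor. Their false calls therefore do not cover differences shared by many probe sets of an array, such as those in RNA quality.

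The arrays of 1 type correlated with r from 0.927 to 0.983 across probe sets in every pair of animals, within or between groups. At most 2.18% of the values of any 2 arrays were identical, so no array had been entered more than once. RNA quality was followed with the control probe sets for the 3' and 5' ends of hexokinase. Their ratio, averaged over the 3 array types on the log2 scale, ranged from 1.87 to 21.2 between animals. The highest ratios divide by 5' values below the floor, such as 5.5, 4.9 and 6.1 (U34A, U34B and U34C) in COP 122. These controls were not set to the floor, so the size of such ratios is uncertain. The same ratio ranged from 1.20 to 3.68 for actin and from 1.03 to 1.33 for GAPDH.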

Results

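Gene expression was measured in the left ventricle of 12 rats aged 15 weeks. The COP and DA groups were inbred strains, and the F1 group came from a cross of both, with 4 animals in each group and 3 arrays per animal. DA rats are known for a higher endurance on the treadmill than COP rats, and the labels name endurance running, Irs2 and Pik3r1 as keywords, so the comparisons ask which cardiac transcripts differ between these strains and where the hybrid lies. The 36 arrays had the same trimmed mean intensity within each type and 14166 probe sets were bright enough to be tested. The arrays of the 12 animals differed in the 3'/5' ratio of the hexokinase control, which grows as RNA or cRNA is shortened from the 5' end. The ratio was 17.0, 1.87, 21.2 and 7.19 in COP 74, 90, 122 and 123, and 1.87, 4.67, 11.8 and 7.73 in DA 56, DA 57, DA 124 and DA 160. In the 4 F1 animals it stayed between 2.56 and 3.49. The 5' signal was below the floor on all arrays of COP 122 and on some of COP 74, COP 123, DA 124 and DA 160. The size of the high ratios is therefore uncertain. On the log2 scale the mean was 3.06 ± 1.59 in COP, 2.41 ± 1.14 in DA and 1.56 ± 0.21 in F1 (SD, n = 4). The mean of F1 differed from that of the parents by -1.18 (exact permutation test, two-sided p = 0.119, 495 splits). That of DA differed from COP by -0.65 (p = 0.543 in the exact permutation test, 70 splits). With 4 animals per group these tests do not show that the groups were alike. They compare means and not the spread, which was smallest in F1.

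**Figure D1:**
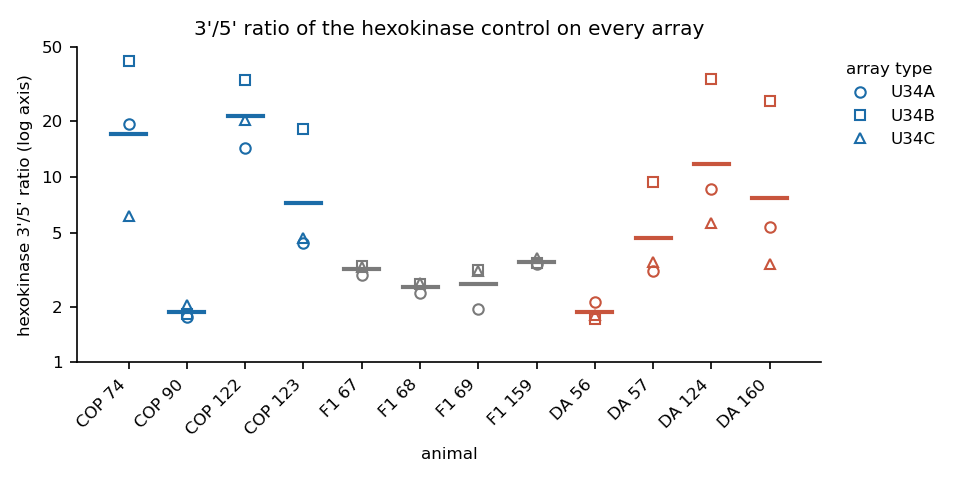
Ratio of the 3' to the 5' hexokinase control probe sets on every array (log axis), by animal, with a symbol per array type and a bar at the geometric mean of the 3 array types. The bars span 1.87 to 21.2 in COP and 1.87 to 11.8 in DA, but only 2.56 to 3.49 in F1.

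Between DA and COP ventricles, several probe sets were near or at the floor in one strain and readily measured in the other. Pla2g12a, a secretory phospholipase A2, was higher in DA (log2 change 5.12 ± 0.16 SE, adjusted p = 3.57e-10, n = 4 and 4). As 3 of 4 COP animals were at the floor and the other at 3.99, this size is set by the floor, and it was 3.07 with a floor at the 50th percentile. Probe sets for the globin genes Hba-a3 and Hbb-bs rose by 4.52 ± 0.22 and 3.85 ± 0.20 on the log2 scale. All COP animals were at the floor for Hba-a3, so its level was at least 23.0-fold higher in DA. The other large rises were in Serhl2, a serine hydrolase (4.33 ± 0.26), and Hs6st1, which sulfates heparan sulfate chains (3.96 ± 0.30, and 1.83 with a floor at the 50th percentile, as 2 of 4 COP animals were at the floor). Ccdc92, a coiled-coil protein, followed at 3.01 ± 0.26. With a floor at the 50th percentile the changes were 2.25 for Hba-a3, 2.83 for Serhl2 and 1.21 for Ccdc92. The other probe set of Pla2g12a rose by 2.08, while that of Hs6st1 differed by -0.46.

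In the opposite direction, Vwa8, which encodes a mitochondrial protein, was at the floor in all 4 DA animals and at least 29.1-fold lower than in COP (log2 change -4.86 ± 0.18, adjusted p = 1.33e-09). Ncoa4, the receptor that delivers ferritin for degradation, differed by -4.65 ± 0.23, with 2 of 4 DA animals at the floor. Both sizes depend on the floor, and with one at the 50th percentile they were -2.68 and -2.82. Myl7, the atrial regulatory myosin light chain, fell from a log2 level of 9.59 ± 0.12 in COP to 6.03 ± 0.39 in DA (SD, n = 4), 11.8-fold (adjusted p = 3.93e-08). Slpi, a secreted protease inhibitor, and Mx2, an interferon-induced GTPase, were lower in DA by -2.74 ± 0.30 and -2.70 ± 0.42. Jund, a subunit of the AP-1 transcription factor, was lower by -2.69 ± 0.41 (adjusted p = 0.00298). Falls between -2.63 and -1.76 were measured for Slc4a1, the anion exchanger of red cells (-2.63), the scaffold protein gene Lin7c (-2.57) and Mrc1, the macrophage mannose receptor (-2.01). The remaining 3 were Tor1b, a torsin ATPase of the endoplasmic reticulum (-1.85), the Golgi membrane protein gene Golm1 (-1.79) and the GABA receptor subunit gene Gabrb2 (-1.76). With the higher floor the changes of Slpi (-0.57), Jund (-0.63) and Tor1b (-0.39) lost their calls, and that of Slc4a1 was -1.29. These falls belong to single probe sets. Other probe sets of Vwa8 (mean 0.54), Ncoa4 (0.28), Mx2 (0.24), Lin7c (0.46) and Mrc1 (0.48) went the other way, and those of Slc4a1 changed by a mean of -0.29.

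Pik3r1, the regulatory subunit of phosphatidylinositol 3-kinase and a keyword of the study, was among the 12 largest rises. It lay at the floor in all 4 COP animals and averaged 5.73 ± 0.27 in DA (log2, SD, n = 4), at least 7.82-fold higher (log2 change 2.97 ± 0.51 SE, adjusted p = 0.00707), with F1 at 4.14 ± 1.02. As COP lay at the floor, the size of this rise depends on it. With the higher floor the change of Pik3r1 was 0.70 (adjusted p = 0.0123). Its call was lost in the 9 animals with a hexokinase ratio under 8 (3.07, adjusted p = 0.106). It was also lost in both settings restricted by animal number. These restrictions of the animals were chosen after the data had been seen. Another Pik3r1 probe set was too dim to be tested, with intensities of 6.8 or lower in the COP animals and of 34.2, 14.5, 4.8 and 7.3 in DA 56, DA 57, DA 124 and DA 160. Irs2, the insulin receptor substrate that is the other keyword gene, showed no difference between the strains (0.01 ± 0.27, adjusted p = 0.998; 6.24 ± 0.51 in COP and 6.24 ± 0.31 in DA). The other Irs2 probe sets were below the filter. Other large rises included the formin gene Fmn1 (2.83 ± 0.57, adjusted p = 0.0215, with 3 of 4 COP animals at the floor, and 1.27 with the higher floor), the ubiquitin ligase subunit Rbx1 (2.24), the RNA helicase Ddx5 (2.24) and Pdp2 (1.99 ± 0.38, adjusted p = 0.0154), a phosphatase that activates pyruvate dehydrogenase. The other probe set of Ddx5 differed by -0.44 and those of Rbx1 by a mean of 0.36. Of the 24 genes with the largest changes, Fmn1 and Pdp2 lost their calls without single animals. For Fmn1 these were COP 74, 122 and 123 and each DA animal, with an adjusted p of up to 0.0726, and for Pdp2 they were COP 74, 122 and 123 and DA 56 and 57 (up to 0.0545).

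**Figure D2:**
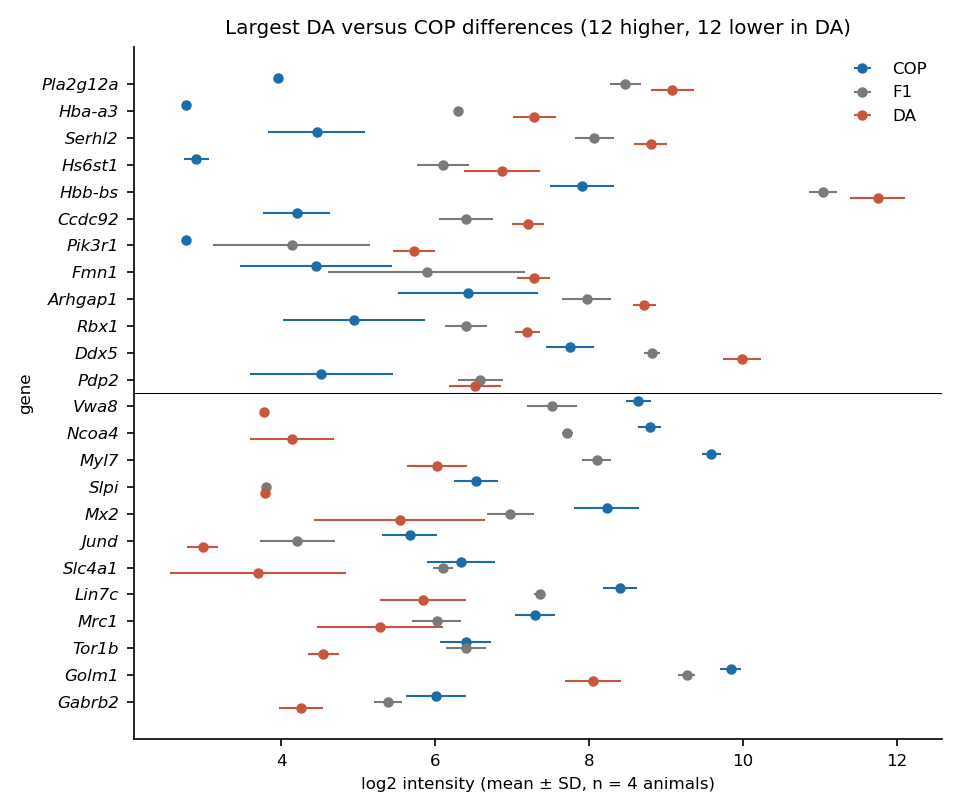
Log2 intensity (mean ± SD, n = 4 animals) in COP, F1 and DA of the 12 genes with the largest rise and the 12 with the largest fall in DA against COP. Pla2g12a spans 3.96 in COP to 9.08 in DA and Vwa8 8.64 in COP to 3.78 in DA, which is the floor of its array type.

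Genes of the immediate early response, which are switched on within minutes of a stimulus, were lower in DA as a group. Of 26 measured, 0 rose and 2 fell over all probe sets, Jund and the nuclear receptor gene Nr4a1 (-1.42 ± 0.30, adjusted p = 0.0292), and 8 fell when adjusted over the list alone (mean change -0.54, adjusted p = 2.49e-05 in camera, 0.130 with an estimated correlation). Nr4a1 lost its call without COP 74, 90, 122 or 123 or without DA 56 or 160 (adjusted p up to 0.0817). The genes of the major histocompatibility complex and antigen presentation were also lower in DA. Of 27 genes 24 had a negative change, 0 rose and 1 fell, the class II gene RT1-Ba (-0.74 ± 0.16, adjusted p = 0.0297; up to 0.102 without COP 74, 122 or 123 or DA 56 or 57), and adjusted over the list alone 1 fell. The adjusted p of this list was 0.00118, and 0.130 with an estimated correlation. Among 7 markers of atrium and conduction tissue 2 fell, Myl7 and the transcription factor gene Tbx5 (-1.08 ± 0.20, adjusted p = 0.0135), and 2 fell adjusted over the list alone. The list had an adjusted p of 0.00096 and one of 0.130 with an estimated correlation. Its brightest members, Pam (-0.06 ± 0.10) and the natriuretic peptide gene Nppa (-0.28 ± 0.17), showed no difference past the spread. With fry these 3 lists and the red cell markers were called, with adjusted p-values of 0.0114, 0.0114, 6.67e-05 and 6.67e-05.

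Shifts downward were also found for 4 other lists, each lost with an estimated correlation. Of 31 extracellular matrix and fibroblast genes, 2 fell, fibronectin (Fn1, -0.62 ± 0.12) and the matrix calcification inhibitor Mgp (-0.48 ± 0.11), and adjusted over the list alone 1 rose and 2 fell (adjusted p = 0.0146, and 0.437 with an estimated correlation). A probe set of the collagen gene Col1a1 rose by 0.70 ± 0.15, while its brightest probe set differed by -0.16 ± 0.17. Of 13 glucocorticoid response genes, 0 passed the test and 1 fell adjusted over the list alone (mean -0.41, adjusted p = 0.0146, and 0.351 with an estimated correlation). Of 59 ribosomal protein genes, 1 rose, the striated muscle form Rpl3l (0.74 ± 0.10, adjusted p = 0.00124), and 2 fell, Rps4y2 (-1.74 ± 0.30) and Rpl3 (-0.48 ± 0.10), and adjusted over the list alone also 1 rose and 2 fell (adjusted p = 0.0158, and 0.470 with an estimated correlation). With the hexokinase ratio as a covariate, an added setting, the ribosomal list had an adjusted p of 0.134. Of 15 endothelial markers, 0 passed, also adjusted over the list alone (mean -0.26, adjusted p = 0.0246, and 0.351 with an estimated correlation), and the brightest, Cav1 (-0.06 ± 0.11) and Eng (0.09 ± 0.10), did not differ past the spread. Fn1 lost its call without COP 123, DA 56 or DA 160 (adjusted p up to 0.0613) and Rpl3 without COP 122, COP 123, DA 56, DA 57 or DA 160 (up to 0.0915). Mgp lost it without any animal but COP 90, F1 67, F1 159 and DA 124 (up to 0.12), and Col1a1 without any but COP 90, F1 69 and F1 159 (up to 0.111). The list calls ended for the extracellular matrix without COP 123 or DA 124 (adjusted p up to 0.178) and for the glucocorticoid response without COP 90, COP 123 or DA 57 (up to 0.0676). They ended for ribosomal proteins without COP 74, COP 122, DA 56 or DA 57 (up to 0.106) and for endothelium without COP 74, COP 123, DA 57 or DA 124 (up to 0.178).

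Metabolic lists shifted slightly upward in DA. The mean change was 0.07 over 80 nuclear genes of oxidative phosphorylation, 0.09 over 18 genes of the TCA cycle and 0.05 over 28 genes of glycolysis and glycogen (adjusted p = 0.0158, 0.0326 and 0.0405), with adjusted p-values of 0.555, 0.470 and 0.351 with an estimated correlation. Within oxidative phosphorylation 1 gene rose, the complex I subunit gene Ndufa10l1 (0.95 ± 0.10, adjusted p = 0.000171), and 1 rose adjusted over the list alone. Within the TCA cycle 0 passed over all probe sets and 1 rose adjusted over the list alone. The 1 glycolytic gene that passed, on either count, fell, enolase (Eno1, -0.73 ± 0.10, adjusted p = 0.000968). After quantile normalization these 3 lists had adjusted p-values of 0.316, 0.0865 and 0.074. Of 29 heat shock and unfolded protein genes, 0 passed over all probe sets, and 1 rose and 1 fell adjusted over the list alone (mean 0.10, adjusted p = 0.0158, and 0.470 with an estimated correlation). With the hexokinase ratio as a covariate the mean change was 0.111 for oxidative phosphorylation and 0.153 for heat shock (adjusted p = 0.000338 and 0.000723). Of 11 clock and output genes, 0 passed on either count (mean 0.46, adjusted p = 0.0146, and 0.437 with an estimated correlation), and with that covariate their mean was 0.61 (adjusted p = 0.000723). This list lost its call without COP 90 (adjusted p = 0.128), whose arrays shared the lowest hexokinase ratio with DA 56, or without COP 123. Oxidative phosphorylation and heat shock lost theirs without COP 90, COP 123, DA 57 or DA 124 (adjusted p up to 0.291 and 0.264), the TCA cycle without COP 123, F1 69, DA 57 or DA 124 (up to 0.663), and glycolysis without COP 90, COP 122, COP 123, F1 69, DA 57 or DA 124 (up to 0.174).

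Among 8 red cell markers, 2 rose and 1 fell on either count. The probe sets of Hba-a3 and Hbb-bs were far higher in DA, while Hba-a1 (-0.08 ± 0.10) and Hbb (-0.13 ± 0.13), the brightest globin probe sets at log2 levels of 14.17 ± 0.17 and 12.30 ± 0.25 in COP, did not differ past the spread. The list's mean change was 0.98 and its median -0.01 (adjusted p = 0.0146 upward, 0.351 with an estimated correlation, and 0.0808 without COP 123).

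The fatty acid list of 40 genes held 2 that passed on either count, acyl-CoA binding protein (Dbi, 0.62 ± 0.14), which rose, and Decr1 (-0.53 ± 0.12), an enzyme of unsaturated fatty acid oxidation, which fell (list adjusted p = 0.777 with an estimated correlation). Lipoprotein lipase (Lpl) fell at 1 probe set (-0.61 ± 0.11, adjusted p = 0.0111), while its brightest differed by 0.14 ± 0.09. In the list of 29 insulin and PI3-kinase signaling genes 1 rose on either count, Pik3r1 (adjusted p = 0.660). In the hypertrophy and fetal program list of 23 genes, the cardiac transcription factor gene Mef2c rose (0.93 ± 0.17, adjusted p = 0.0110), 1 on either count (list 0.640). Of 40 antioxidant genes, plasma glutathione peroxidase (Gpx3) fell (-0.74 ± 0.14) and 3 rose and 2 fell adjusted over the list alone (list 0.660). A dimmer probe set of the glutathione transferase gene Gstt2 rose (1.31 ± 0.29, adjusted p = 0.0427) while its brightest differed by -0.72 ± 0.24. No member passed, over all probe sets or adjusted over the list alone, in the lists of sarcomere genes (28, adjusted p = 0.123), calcium handling and ion channels (34, 0.203), adrenergic signaling (28, 0.322), vasoactive peptides and nitric oxide (17, 0.640) and thyroid hormone response (8, 0.272). Gpx3 lost its call without COP 74 or COP 123 (adjusted p up to 0.055), Dbi without any animal but COP 122, F1 68 and DA 56 (up to 0.108), Decr1 without any but COP 90 (up to 0.12) and Gstt2 without any but COP 90 and DA 160 (up to 0.133).

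Markers of other cell types gave no call over all probe sets for smooth muscle and pericytes (9 genes, adjusted p = 0.993), leukocytes (14, 0.298), adipocytes (7, 0.696) and nerve and Schwann cells (7, 0.863). Adjusted over the list alone, 1 leukocyte and 1 nerve marker fell. For skeletal muscle markers (7, 0.470) a dimmer probe set of the fast myosin gene Myh1 rose (1.92 ± 0.40, adjusted p = 0.0280, up to 0.0811 without COP 123 or any DA animal) while the brightest differed by -0.32 ± 0.30. The brightest markers of these types differed by 0.05 ± 0.10 (Des), -0.12 ± 0.25 (Rgs5), -0.36 ± 0.15 (Fcer1g), 0.01 ± 0.15 (Cd68), -0.17 ± 0.17 (Lep), 0.20 ± 0.16 (Aqp7), -0.05 ± 0.13 (Ckm), 0.01 ± 0.15 (Pmp22) and 0.04 ± 0.15 (Uchl1). Of the lists too small for a test, mesothelium and epithelium had 3 measured genes with 0 calls (Krt19 0.34 ± 0.45, Wt1 -0.17 ± 0.24), the mitochondrial genome 3 with 0 calls, and the sex-linked list only Rps4y2, which RefSeq places on chromosome 4 of GRCr8. Median, mean and test differed in sign for the lists of insulin signaling, hypertrophy, smooth muscle, skeletal muscle and red cell genes.

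**Figure D3:**
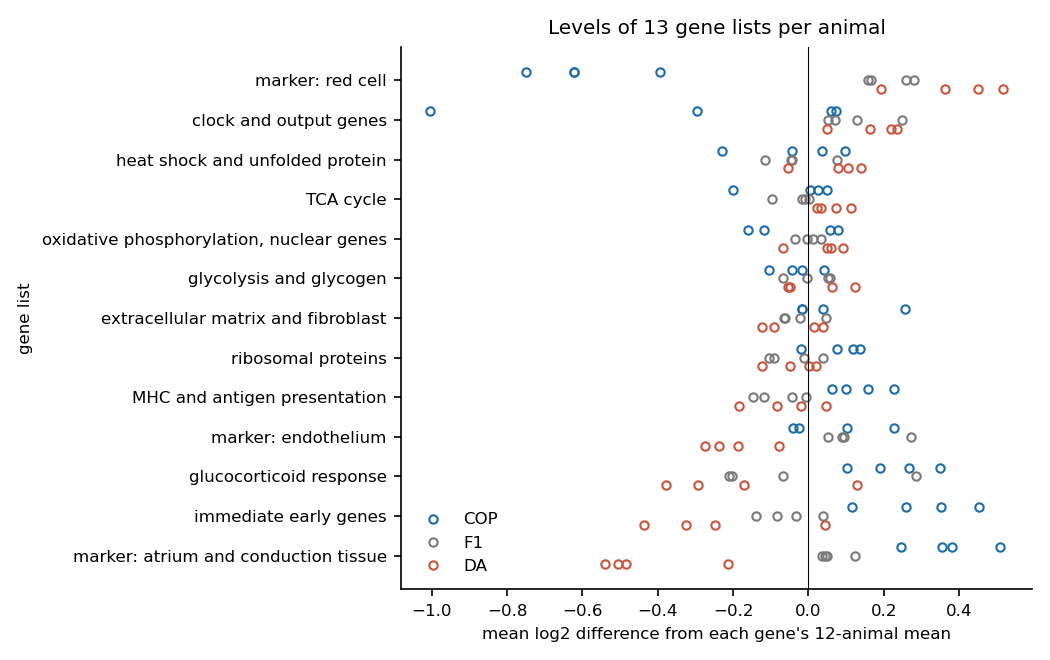
Level of the 13 gene lists called between DA and COP in each animal, as the mean over the list's genes of the log2 difference from the gene's mean over 12 animals (x axis), with 1 point per animal of COP, F1 or DA. The 4 DA animals lie at -0.54 to -0.21 for atrial markers and the 4 COP animals at 0.24 to 0.51.

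In all, 103 probe sets were higher and 101 lower in DA (62 and 70 genes, and 56 probe sets without a single symbol), 102 of them by at least 2-fold, and 1457 probe sets (10.3%) had an unadjusted p under 0.05. For 203 of the 204 all animals of one strain lay above all of the other, as did 6.07% of all tested probe sets, where chance gives 2 of 70. Of 957 genes on chromosome 1 of GRCr8, 3 were called (0.314%, against 1.54% elsewhere; Fisher's exact test, adjusted p = 0.0201), and of 690 on chromosome 10, 18 (2.61% against 1.26%, adjusted p = 0.0984). Counting any probe set of a gene, chromosome 10 had 25 (3.62%, adjusted p = 0.00851) and chromosome 1 had 5 (adjusted p = 0.00915). These Fisher tests take genes as independent, which neighboring genes are not, so they are descriptive. The finding for chromosome 1 was lost without COP 90, COP 123, F1 68, F1 69, DA 57 or DA 124, and chromosome 10 passed without COP 74, F1 68, F1 159, DA 56 or DA 160. The other probe sets of the same genes had a median change of 0.291 times that of the called one over 63 genes. Of these 97 probe sets, 76 had the same sign and 14 were called in the same direction. Those of Ncoa4 (0.28), Vwa8 (0.54), Lin7c (0.46), Mx2 (0.24), Mrc1 (0.48), Hs6st1 (-0.46) and Ddx5 (-0.44) went the other way, while Pla2g12a was called at both of its probe sets (mean of the other 2.08). Fitted within the animals numbered under 100 (2 COP and 2 DA) 37 probe sets passed, and within those over 100 (also 2 and 2) 6, against 204 with all animals and 222 with the number class as a covariate.

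The hybrid was set against each parent in turn. Against COP, F1 ventricles had higher levels of Pla2g12a (log2 change 4.50 ± 0.16, adjusted p = 2.02e-09), Serhl2 (3.61 ± 0.26), Hba-a3 (3.54 ± 0.22, at least 11.6-fold) and Hs6st1 (adjusted p = 0.000133, with a change of 1.07 at the higher floor, where that of Hba-a3 was 1.27). Abcc9, the sulfonylurea receptor subunit of ATP-sensitive potassium channels, rose by 3.98 ± 0.38 (adjusted p = 0.000133, n = 4 and 4). As COP was near the floor this size depends on it, and was 2.10 with a floor at the 50th percentile. Slpi fell to near the floor in F1 (-2.72 ± 0.30) and Myl7 was lower by -1.49 ± 0.18. Falls were also called for Mettl16, an RNA methyltransferase (-1.91 ± 0.39, adjusted p = 0.0423), the transmembrane protein gene Tmem116 (-1.55 ± 0.33, adjusted p = 0.0455) and the transcription factor gene Sox21 (-1.51 ± 0.29, adjusted p = 0.0296). At the higher floor the falls of Slpi (-0.57) and Sox21 (-0.20) lost their calls. Irs2 (0.38 ± 0.27) and Pik3r1 (1.37 ± 0.51, adjusted p = 0.230) did not pass. Of the 27 lists, 4 were called with camera, antigen presentation downward (2 of 27 genes lower over all probe sets and 13 adjusted over the list alone) and immediate early genes downward (1 of 26, and 3 over the list alone). Ribosomal proteins were called downward, although over all probe sets 1 of 59 was higher and 0 lower (1 higher and 4 lower over the list alone), and red cell markers upward (2 of 8 higher and 0 lower, and 2 and 1 over the list alone). Their adjusted p-values were 0.00101, 0.003, 0.003 and 0.0140, and 0.268, 0.459, 0.508 and 0.459 with an estimated correlation. With fry 3 were called, antigen presentation (adjusted p = 0.00549), red cell markers (0.000436) and atrial markers (0.0322). Median, mean and test differed in sign for the lists of fatty acid, TCA cycle, endothelial, adipocyte and nerve genes. In all, 55 probe sets were higher and 61 lower in F1, 54 of them by at least 2-fold, with an unadjusted p under 0.05 at 2119 (15.0%). The count of 116 was 230 without COP 90 and 48 to 77 without any other COP or any F1 animal. Mettl16 lost its call without any animal but COP 74, F1 67, F1 69 and DA 56 (adjusted p up to 0.12), Tmem116 without any but COP 74, F1 69 and DA 124 (up to 0.127), and Sox21 without COP 74, COP 122, COP 123, F1 68, F1 69 or F1 159 (up to 0.0982).

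Against DA, the largest rises in F1 were in Vwa8 and Ncoa4, which were at or near the floor in DA. Vwa8 was at least 13.4-fold higher (log2 change 3.74 ± 0.18, adjusted p = 8.97e-08, n = 4 and 4) and Ncoa4 rose by 3.58 ± 0.23, and with a floor at the 50th percentile the changes were 1.55 and 1.76. Abcc9 (2.52 ± 0.38, adjusted p = 0.00585), Slc4a1 (2.40 ± 0.46, adjusted p = 0.0278) and Tie1, a receptor of endothelial cells (2.30 ± 0.45, adjusted p = 0.0334), were also higher in F1. Mettl16 (-2.08 ± 0.39), Tmem116 (-1.58 ± 0.33) and Sox21 (-1.58 ± 0.29) were lower in F1 than in DA as they were against COP. Atxn2, which encodes the RNA-binding protein ataxin, was also lower than in DA (-1.37 ± 0.22, adjusted p = 0.00834). With a floor at the 50th percentile the change of Sox21 was -0.26 and its call ended. Ddx5 was lower by -1.17 ± 0.16. Irs2 (0.37 ± 0.27) and Pik3r1 (-1.60 ± 0.51, adjusted p = 0.150) did not pass. With camera 0 of 27 lists were called at either correlation, and with fry 1, the atrial markers (adjusted p = 0.00877). Here median, mean and test differed in sign for fatty acid, sarcomere, calcium handling, hypertrophy, antioxidant, leukocyte and red cell genes. In all, 65 probe sets were higher and 58 lower, with an unadjusted p under 0.05 at 2313 (16.3%). The count of 123 was 262 without DA 56 and 46 to 75 without any other DA or any F1 animal. Calls ended for Mettl16 without F1 68, F1 159, DA 57 or DA 160 (adjusted p up to 0.0933), for Tmem116 without COP 122, F1 67, F1 68, F1 159, DA 57 or DA 160 (up to 0.119) and for Sox21 without F1 68, F1 69, F1 159, DA 57 or DA 124 (up to 0.0765). They ended for Slc4a1 without any F1 animal, DA 124 or DA 160 (up to 0.0907) and for Tie1 without F1 67, F1 68, F1 159, DA 57, DA 124 or DA 160 (up to 0.103).

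Departures of the hybrid from the mid-parent were led by Abcc9, which averaged 7.14 ± 0.11 in F1, 3.16 ± 0.34 in COP and 4.62 ± 0.77 in DA (log2, SD, n = 4), 3.25 ± 0.33 SE above the mid-parent (adjusted p = 0.000719). Clasrp, a splicing regulator, was at 6.32 ± 0.17 in F1 and near 4.2 in both parents (4.19 ± 0.25 in COP, 4.23 ± 0.14 in DA; 2.11 ± 0.25 SE above, adjusted p = 0.00115), but with a floor at the 50th percentile its departure was 0.36 and its call ended (adjusted p = 0.116). Socs2, a suppressor of cytokine signaling, lay above both parents in F1 (7.51 ± 0.08, against 6.39 ± 0.33 in COP and 5.27 ± 0.25 in DA; adjusted p = 0.000719). Pla2g12a was 1.94 ± 0.14 above on the log2 scale, but 0.33 with the mid-parent taken on the linear scale (adjusted p = 0.281). Further rises were called for the splicing factor Ptbp1 (2.23 ± 0.47, adjusted p = 0.0491) and the GTP-binding protein gene Gtpbp6 (1.55 ± 0.29, adjusted p = 0.0317). Ptbp1 and Gtpbp6 lost their calls with the linear mid-parent (adjusted p = 0.102 and 0.0504). Other probe sets of these genes, brighter on average, departed by a mean of 0.57 for Abcc9, 0.83 for Clasrp, 0.19 for Ptbp1 and -0.07 for Gtpbp6, and 0 of them were called in the same direction. The other one of Pla2g12a departed by 0.85 and was called.

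Below the mid-parent were Mettl16 (-1.99 ± 0.34, adjusted p = 0.0174), Tmem116 (-1.57 ± 0.28), Sox21 (-1.54 ± 0.25), Slpi (-1.35 ± 0.26, adjusted p = 0.0343), Atxn2 (-1.31 ± 0.19, adjusted p = 0.00568, with another probe set at -0.06) and the membrane glycoprotein gene Ginm1 (-1.22 ± 0.21). Irs2 (0.37 ± 0.24, adjusted p = 0.432) and Pik3r1 (-0.11 ± 0.44, adjusted p = 0.925) did not depart from it past the spread. In all, 39 probe sets were above and 51 below (25 and 35 genes, and 28 without a single symbol). Of these 90, 29 had all 4 F1 animals above all 8 parents and 45 had all 4 below. Over all tested probe sets F1 lay outside the parents in this way at 2.78%, where chance gives 0.404%. With camera and with fry 0 of 27 lists were called. The lowest adjusted p was 0.0584, for vasoactive peptides and nitric oxide (upward, mean 0.35) and for antigen presentation (downward, mean -0.12), and 2415 probe sets (17.0%) had an unadjusted p under 0.05. Median, mean and test differed in sign for the lists of fatty acid, glycolysis, oxidative phosphorylation, hypertrophy and antioxidant genes. The F1 arrays had the narrowest range of hexokinase ratios. Without COP 90 or DA 56, the parents with the lowest ratio, 167 and 210 probe sets were called, and 43, 27, 45 and 21 without F1 67, 68, 69 and 159, with 55, 52, 46 and 43 without COP 122, COP 123, DA 57 and DA 160. Calls ended for Mettl16 without F1 68 or F1 159 (adjusted p up to 0.0877), for Sox21 without F1 68, F1 69 or F1 159 (up to 0.0646), for Ginm1 without F1 67, F1 69 or F1 159 (up to 0.0732) and for Tmem116 without COP 123, F1 67, F1 68, F1 159, DA 57 or DA 160 (up to 0.0873). They ended for Gtpbp6 without COP 123, DA 57, DA 160 or any F1 animal (up to 0.118), for Ptbp1 without any animal but COP 90 and DA 56 (up to 0.144) and for Slpi without any but DA 56 and DA 124 (up to 0.0992). With a floor at the 50th percentile the departures of Sox21 (-0.23), Slpi (-0.28) and Ptbp1 (1.07) also lost their calls.

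At the 204 probe sets that differed between the parents, F1 lay close to the middle. The median position per F1 animal was 0.475, 0.518, 0.525 and 0.502 in F1 67, 68, 69 and 159, 0.505 ± 0.022 (SD, n = 4), on the scale where COP is 0 and DA is 1. This SD covers only the F1 animals, all placed against the same parent means. With 1 animal left out the mean was 0.460 (without DA 56) to 0.584 (without COP 90). Of the 204, 187 had the F1 mean between the parents, 5 had it beyond DA and 12 beyond COP, and 58.8% lay between 0.25 and 0.75. The median was 0.572 over probe sets higher in DA and 0.408 over those higher in COP, so that F1 was on the log2 scale nearer to the higher parent. Single genes spread widely. Tor1b (0.00) and Slc4a1 (0.09) were at the COP level in F1, Slpi (0.99) and Pdp2 (1.04) at the DA level, and Ddx5 (0.48), Pik3r1 (0.46) and Jund (0.54) near the middle. The globin probe sets Hba-a3 (0.78) and Hbb-bs (0.81) lay nearer to DA, and Vwa8 (0.23) and Ncoa4 (0.23) nearer to COP. These are positions on the log2 scale, and for Hba-a3, Pik3r1 and Vwa8 they depend on the floor, at which all animals of 1 parent lay. That of Slpi also does, as 3 of 4 F1 and 3 of 4 DA animals were at the floor. For Ncoa4 and Slc4a1, 2 of 4 DA animals were at it. Slpi, Tor1b and Jund were not called between DA and COP with a floor at the 50th percentile.

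**Figure D4:**
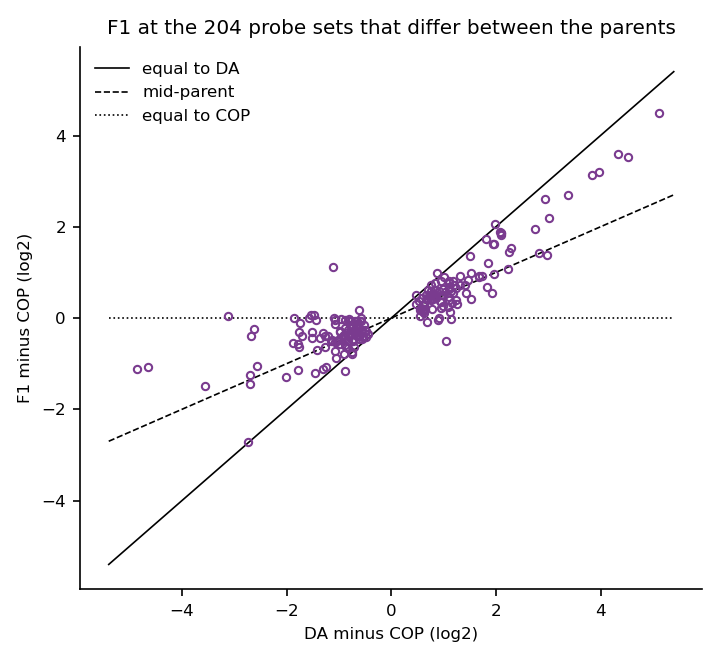
Difference of F1 from COP (y axis, log2) against that of DA from COP (x axis, log2) at the 204 probe sets called between DA and COP, 1 point per probe set, with lines where F1 would equal DA, the mid-parent or COP. Of the points, 187 lie between the lines for COP and DA.

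Clock genes, whose products drive daily rhythms, varied within COP. Dbp, an output gene of the clock, stood at 3.10 in COP 90 and at 7.53 to 8.33 in the other 3 COP animals (log2), and at 7.57 to 8.70 in the F1 and DA animals. Nr1d1 was lower in COP 90 than the mean of the other 3 by -1.38 and Nr1d2 by -1.20, though Nr1d2 was nearly as low in COP 123 (6.56) as in COP 90 (6.41). Bhlhe41 (-0.87), Per2 (-0.66) and Tef (-0.56) were also lower in COP 90 than that mean, while Hlf differed by -0.04.

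**Figure D5:**
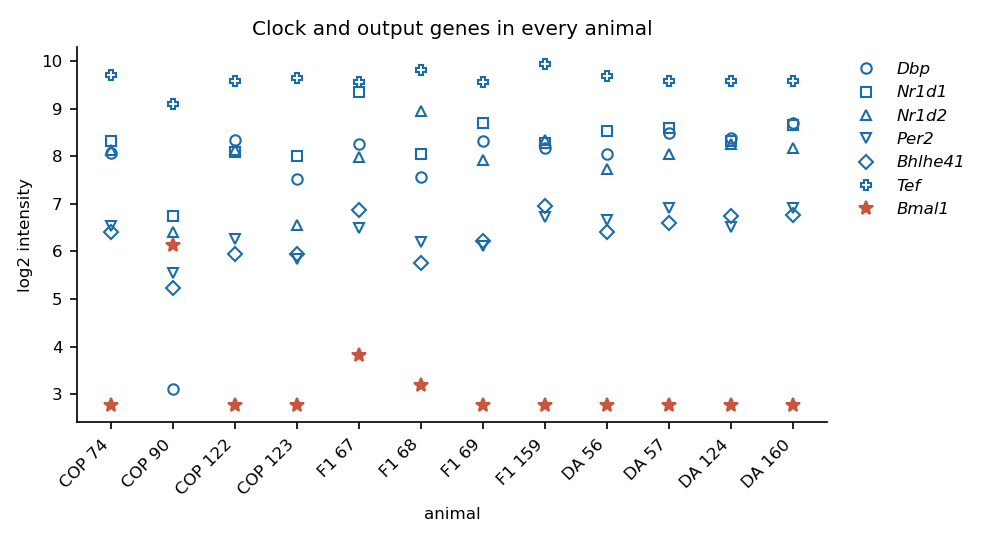
Log2 intensity of 7 clock genes in each of the 12 animals, with circles, squares, triangles, diamonds and crosses for genes of the output or repressor arm and stars for Bmal1, of the activator arm, whose probe set was too dim to be tested. In COP 90 Dbp lies at 3.10 and Bmal1 at 6.14, while Bmal1 is at or near its floor of 2.77 elsewhere, with a highest value of 3.83 in F1 67.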

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

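Of the tests in this part, those of collection time and of the 3'/5' ratio for the clock genes of COP 90 were chosen after the result was seen, as were the fits within the number classes, the bootstrap interval for the position of COP 90 and its comparison with F1. The other tests were set beforehand, but that the interval of the other probe sets had to lie below 0.25 was asked only after its value was seen. In 307 groups of 4 animals, 1 animal stood far from the other 3 by Dixon's ratio in 19, and chance gives about 1 in 20 groups.

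F1 departed from the mid-parent at 90 probe sets, and the first explanation weighed was the 3'/5' ratio of the arrays. With the log2 hexokinase ratio as a covariate the median share kept of the called changes was 0.967 (0.958 to 0.999 without each animal in turn). This passed the limit set beforehand against this cause (over 0.75), although only 57 of the 90 were called again. The calls were made without the covariate, and probe sets that follow the ratio vary within COP and DA and are called less readily. A high share was therefore likely beforehand and does not decide whether the ratio is a cause. Of 100 splits of the 12 animals into 3 groups of 4, the real split and drawn ones, 2 gave as many calls, the real one included. As many calls were thus uncommon, but chance is not excluded. The highest other split had COP 122, DA 57, DA 124 and DA 160 in the place of F1 and gave 212. The split with all DA animals in that place gave 68. What these splits follow was not tested. Other probe sets of the same genes changed by a median of 0.156 times the called change (bootstrap 95% interval 0.0168 to 0.338, 27 genes), and 2 of 51 were called in the same direction. This median met the limit set beforehand for effects on single probe sets (under 0.25), while the interval, asked for only afterwards, includes it. The called probe sets were also chosen for their change, which lowers this ratio. Such effects can therefore not be told apart from changes of the transcript. A true departure of the hybrid, in single transcripts or splice forms, stays open and was not tested.

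Between DA and COP 204 probe sets were called. With the hexokinase ratio as a covariate the median share of the change kept was 0.993 (0.982 to 1.02 without each animal in turn). This also passed the limit of 0.75, and 192 of the 204 were called again. As these calls too were made without the covariate, a high share was likely beforehand and does not decide whether the ratio is a cause. The real split gave the most calls among 35 (1 of 35, the real one), and no smaller share is possible with 35 splits. The split of COP 74, COP 90, DA 56 and DA 57 from the rest, which follows animal numbers under and over 100, gave 203. The rank of the real split can therefore not exclude chance. With this number class as a covariate DA against COP gave 222, and 37 and 6 within the classes. Other probe sets of the same genes changed by a median of 0.291 times the called change (0.168 to 0.407, 63 genes). Of these 97 probe sets, 76 had the same sign and 14 were called in the same direction. The ratio was over 0.5 for 21 genes and under 0.25 for 30. The median met neither limit set beforehand (under 0.25 with variants under the probes, over 0.5 without). Over the set, such variants can therefore not be told apart from differences in transcript level. True strain differences stay open.

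The clock genes of COP 90 stood apart from those of the other COP animals, with Dbp lower by -4.87 and Bmal1 higher by 3.37 (log2), while the output gene Hlf (-0.04) and the other activator measured, Npas2 (-0.13), differed little. Over 7 output and 2 activator genes, taken from all probe sets because the activators were too dim to be tested, the change of the output genes minus that of the activators was -2.99 in COP 90 and -0.83 to 1.17 in the other 11 animals, each against the rest of its group. These values had prompted the question and rest largely on Dbp and Bmal1, so they do not test another time of tissue collection, which stays open. DA 56, with the same hexokinase ratio, had 0.0457 times this difference, which argues against the ratio as the cause. The median position of COP 90 between the strains was 0.220 (bootstrap 95% interval 0.123 to 0.276, 210 probe sets). COP 74, COP 122 and COP 123, each placed by calls made without it, stood at 0.05, 0.07 and 0.06, so COP 90 lay nearer to DA. It was still 0.319 below the lowest F1 animal over the same probe sets (interval 0.248 to 0.415), which argues against an F1 or DA animal under its label. Another wrong label cannot be told apart because the first interval includes the limit of 0.25 set beforehand. Both intervals resample probe sets and do not cover the variation between animals.

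For the comparisons of F1 with each parent, the real split gave the most calls, with 116 against COP (1 of 35 splits, highest other 1) and 123 against DA (1 of 35, highest other 2). This argues against chance for both counts, although no smaller share is possible with 35 splits.

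The animals that stood apart in their group are given as values only. For the smooth muscle list DA 56 had a mean level of -0.42 (others -0.08 to -0.02). For the atrial list F1 69 had 0.12 (others 0.04 to 0.05) and DA 160 had -0.21 (others -0.54 to -0.49). For the mesothelial list DA 56 had 0.32 (others -0.35 to -0.28). In log2 intensity, Pla2g12a was 3.99 in COP 74 with the other COP animals at the floor, and Hs6st1 was 5.59 in F1 67 (others 6.23 to 6.33). Ccdc92 was 4.85 in COP 123 (others 3.95 to 4.04) and Fmn1 5.94 in COP 90 with the others at the floor. Arhgap1 was 5.08 in COP 123 (others 6.69 to 6.98). Pdp2 was 5.91 in COP 90 (others 3.89 to 4.20) and 7.01 in F1 68 (others up to 6.47). Slpi was 3.90 in F1 67 and 3.83 in DA 160, with the others at the floor. Lin7c was 7.47 in F1 67 (others 7.31 to 7.33). Atxn2 was 7.40 in DA 124 (others 7.80 to 7.88) and Ptbp1 7.51 in DA 56 (others 4.46 to 4.70). Lpl was 11.78 in COP 122 (others 11.83 to 11.84), Decr1 10.06 in F1 68 (others 10.24 to 10.26) and Ndufa10l1 11.02 in DA 56 (others 11.23 to 11.26).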

How the results depend on the processing

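The settings with the hexokinase ratio and those within a number class were chosen after the data were seen. No paired analysis was possible because no animal number was shared by 2 groups. The counts of calls below are for DA against COP, F1 against COP, F1 against DA and F1 against the mid-parent, in this order, beside 204, 116, 123 and 90. Quantile normalization gave 212, 146, 160 and 133, a common median 195, 109, 105 and 103, the number class as a covariate 222, 97, 128 and 78, and the hexokinase ratio as a covariate 245, 110, 161 and 98, of which 192, 61, 108 and 57 were among the calls without it. Array weights gave 206, 343 and 448 for the 3 F1 comparisons, no variance trend 77 for F1 against COP and 58 against the mid-parent, and a fit of COP and DA alone 110. The 9 animals with a hexokinase ratio under 8 gave 85, 53, 74 and 54, those numbered under 100 gave 37, 4, 9 and 2, and those over 100, with a single F1 animal assumed to vary like the others, gave 6, 1, 0 and 0 in limma (for the last 2, 1316 and 1335 at an unadjusted p under 0.05). Fewer animals were fitted in these settings. Without each animal in turn the counts were 141 to 210, 48 to 230, 46 to 262 and 21 to 210. The highest of the F1 counts came without COP 90 (230), without DA 56 (262) and without DA 56 (210), and the lowest without F1 159 (48), F1 68 (46) and F1 159 (21). The cause was not tested.

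The position of F1, 0.505, was 0.583 in the animals with a low ratio, 0.655 in those over 100 and 0.471 on the linear scale, and 0.460 (without DA 56) to 0.584 (without COP 90) with 1 animal left out. Of the gene lists, 13 were called between DA and COP with the preset correlation, 0 with an estimated one, 4 with fry, 6 under and 7 over number 100, and 4 (without COP 123) to 13 with 1 animal left out, with 8, 6 and 7 without COP 90, DA 57 and DA 124. Against the mid-parent 0 were called, but 2 with the number class and 2 with the hexokinase ratio as a covariate, 1 with a low ratio, 6 with all probe sets of a gene and 0 to 2 with 1 animal left out (2 without F1 67 or DA 56, 1 without COP 122, COP 123 or F1 68). By chromosome, 1 differed, 2 (also chromosome 10) when any probe set of a gene counted, and 0 to 2 with 1 animal left out. Among named genes and list members the only reversal in these settings was Hba-a3 against the mid-parent, -0.0658 with the mid-parent on the linear scale (1.28 on the log2 scale), a scale on which the mid-parent lies higher. The mid-parent calls of Pla2g12a (0.33), Hbb-bs (0.15), Ptbp1 (1.74) and Gtpbp6 (1.40) were also lost there. Pik3r1 between DA and COP kept its call without each animal in turn, with a highest adjusted p of 0.0351, but not within the number classes (adjusted p = 0.325 and 0.249). At a stricter filter its probe set was not tested. Dim signals limit the values near the floor, since a floor at the 50th percentile lowered the DA against COP change of Pik3r1 to 0.70 and ended the calls of Slpi (-0.57), Jund (-0.63) and Tor1b (-0.39). It also ended those of Slpi (-0.57) and Sox21 (-0.20) for F1 against COP, Sox21 (-0.26) for F1 against DA, and Clasrp (0.36), Ptbp1 (1.07), Sox21 (-0.23), Slpi (-0.28) and Hba-a3 (0.14) for F1 against the mid-parent.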

Other observations

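Of the genes in this part, all were chosen after their values were seen, while the test of X-linked genes was set beforehand. Among the fixed lists, 6 members departed from the mid-parent in F1 at the brightest probe set of their gene, and others, such as Abcc9, only at a dimmer one. The class II antigen gene RT1-Da had a lower mean in F1 than in either parent, at 8.48 ± 0.21 against 9.62 ± 0.26 in COP and 9.08 ± 0.23 in DA (log2, SD, n = 4). Its call was against the mid-parent (-0.87 ± 0.14 SE, adjusted p = 0.0101). Calreticulin (Calr), a calcium-binding chaperone, differed by -0.73 ± 0.12 (adjusted p = 0.0142), Mef2a, a cardiac transcription factor gene, by -0.62 ± 0.12 (adjusted p = 0.0323) and the matrix proteoglycan gene Dcn by -0.44 ± 0.09 (adjusted p = 0.044). Above the mid-parent were Hba-a3 (1.28 ± 0.19) and Hbb-bs (1.21 ± 0.18, adjusted p = 0.00732), both between the parents. With the mid-parent on the linear scale these were -0.07 and 0.15 (adjusted p = 0.906 and 0.715), so the departures rest on the log2 scale. RT1-Da lost its call without F1 68 (adjusted p = 0.0608), Calr without F1 68, F1 69 or F1 159 (up to 0.0721), Hba-a3 and Hbb-bs without F1 159 (0.0541 and 0.0517), Mef2a without COP 123, F1 68, F1 69, F1 159, DA 57 or DA 160 (up to 0.11), and Dcn without any animal but COP 90 and DA 56 (up to 0.139).

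Genes of vasoactive peptides and nitric oxide lay above the mid-parent in 14 of 17 cases, with an adjusted p of 0.0584 for the list, and 0 passed singly in limma, also adjusted over the list alone. Of antigen presentation genes 1 of 27 was lower over all probe sets and 6 adjusted over the list alone (list adjusted p = 0.0584, and 0.619 with an estimated correlation). With the number class as a covariate, camera called both lists (adjusted p = 0.0395 for vasoactive peptides and 0.0362 for antigen presentation). Without that covariate neither was called with the correlation estimated or with fry.

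Male F1 animals would carry only the X chromosome of their mother, which would put X-linked genes at the level of 1 parent. Of 203 genes on the X chromosome of GRCr8, 0 were called between DA and COP in limma (1.42% elsewhere), so the position of F1 at such genes was not tested and the sex and the direction of the cross stay open.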
